A study of Mus musculus with 4 samples.

How the data were processed

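Bone marrow cells of 10-week-old C57BL/6 mice were enriched for B220+ cells with magnetic particles and run on the 10x Chromium platform, per the labels' protocols. The deposited data hold 4 libraries, an expression library and a B cell receptor library for each of 2 genotypes. The genotypes are 56R, in which mice carry a knocked-in immunoglobulin heavy chain that binds DNA, and Laptm5KO56R, in which Laptm5 is also knocked out. The series' design text speaks of 3 pairs of mice, and the labels do not say how many mice went into a library, so each genotype was treated as 1 sample per assay.

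The authors deposited UMI counts per gene and barcode from Cell Ranger 6.1.1, per the file headers, for barcodes already called as cells. CASAVA 1.8, Cell Ranger, Seurat and the mouse build mm10 are named in the submitters' processing notes, with no role given for each. The receptor tables, as deposited, list assembled contigs with UMI counts and read counts, the caller's cell, confidence and productive marks, V, J and constant genes and the CDR3 sequence. The Cell Ranger version behind the receptor tables is not given in the sources used here. The labels name a 3' kit for all 4 libraries, including the receptor libraries, and how receptor transcripts were amplified is not given in the sources used here. Gene positions come from GENCODE M21 (build GRCm38), in which 31107 of the 31253 features (99.5%) were found by Ensembl identifier.

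Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. This filter removed 940 barcodes (15.7%) of the 56R library and 360 (5.53%) of the Laptm5KO56R library for too few genes. Scrublet (as provided in scanpy 1.11.5) marked 5 cells (0.0991%) and 3 cells (0.0489%) as doublets, which is too few to count as a working doublet call, so a setting without the highest 5% of doublet scores in each library was added. As a check of depth, UMIs of Laptm5KO56R cells were drawn at random with 1 fraction for all classes, 0.740, which is the ratio of median UMIs in cycling pre-B-like cells (1783 in 56R and 2408.5 in Laptm5KO56R). A further setting used the ratio of each class, set to 1 where it was above 1. In both settings the minimum of 500 genes was applied again, with a minimum of 500 UMIs that the first filter did not have. The 5042 and 6136 kept cells were clustered together with scanpy 1.11.5 on Python 3.11.15. The steps were 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1, without correction between libraries, and gave 18 clusters. Immunoglobulin, mitochondrial, ribosomal-protein and Laptm5 genes were left out of the clustering. Clusters were named from 14 marker lists, and leading genes were ranked by the ratio of CPM (UMI counts scaled by their total), with 20 CPM added, among genes with at least 50 UMIs in the cluster. The lead of the small pre-B-like cluster holds only Rag1 and Il2ra of its list, with Il7r also detected at 755 CPM, and 1 of the cycling clusters was led by histone genes. Cluster 4 had markers of both the immature and the mature lists among its 10 leading genes, so it is compared by its number, and the gene rule written for the immature class was applied to it.

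With 1 library per genotype and assay, no test between genotypes was possible, and no p-value, standard error across mice or number of altered genes is given. Counts were summed over the cells of a class in each library and scaled to CPM. Intervals are 95% intervals: exact Poisson for a level, exact binomial (Clopper-Pearson) for a share, exact conditional binomial for a ratio of counts, and a normal approximation for a difference or a ratio of shares. They cover counting error only. A count of 0 was set to a floor of 3 counts for a fold. Expression was compared in the 4 B-lineage classes with at least 200 cells in each library.

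Before the data were examined, the samples, the gene lists, the rule for named genes and part of the alternatives were fixed, and the other alternatives (thinning, removal of the highest doublet scores, of Xist-positive or Jchain-rich cells or of 1 heavy chain, and heavy chains or contigs of any caller verdict on barcodes of the expression library) were added after the data were seen. Named genes needed at least 200 UMIs over both libraries and were not immunoglobulin, mitochondrial, ribosomal-protein genes or Laptm5. They were ranked by the bound of the log2 interval nearest 0. The 12 highest and 12 lowest were taken in cluster 4 and the 6 highest and 6 lowest in the other classes, together with genes at least 1.5-fold different in 1 direction in all 4 classes. For each of 23 fixed lists, the median log2 ratio of members with at least 50 UMIs was set against 10000 random lists of the same size, matched on expression in 20 bins. The lists cover PI3K-AKT-PTEN and NEDD4 ligases, proapoptotic and antiapoptotic genes, p53 targets, the FOXO program, receptor signalling, immediate early genes, NF-kB targets, recombination and editing, the surrogate light chain, cell cycle, interferon response, MHC classes I and II, unfolded protein response, heat shock, lysosome, glycolysis, migration, BAFF receptors and maturation, immunoglobulin constant genes, mitochondrially encoded genes and ribosomal proteins. Near-identical genes (Hspa1a with Hspa1b, histone genes, Iglc2 with Iglc3) can share reads, so their values are uncertain.

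For receptors, productive, high-confidence contigs of at least 2 UMIs on barcodes called as cells were used, which left 4106 cells in the 56R library and 5310 in the Laptm5KO56R library. Receptor and expression libraries were to be joined only if at least 50% of receptor cells were also barcodes of the expression library of the same genotype. The shares were 35.6% (1464 of 4115 cells) and 50.8% (2701 of 5317 cells), against 25 and 40 cells found in the library of the other genotype, so the libraries were not joined for the report. V genes were named as the 8 most used over both libraries and the 4 with the largest and 4 with the smallest ratio of shares among those with at least 50 cells over both libraries. Alternatives covered the cell filter, doublets, clustering resolution, centring per library, immunoglobulin genes in clustering, scaling (including TMM factors from edgeR 4.0.16 on R 4.3.3), UMI minima and contig filters. The ratio step was tested on simulated counts with 200 genes altered 2-fold. Of the genes raised 2-fold it recovered 100% in cycling pre-B-like cells (2728 genes run), 97% in small pre-B-like cells (1251 genes), 100% in cluster 4 (987 genes) and 99% in mature B-like cells (908 genes). Of the genes lowered 2-fold it recovered 70%, 56%, 56% and 57% in the same order.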

Results

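Single-cell transcriptomes and B cell receptor contigs were measured in B220+ bone marrow cells of 56R mice, whose B cells carry a knocked-in anti-DNA heavy chain, and of Laptm5KO56R mice, which also lack LAPTM5, a lysosomal transmembrane protein of blood cells. The 56R expression library held 10652247 UMIs over 5995 barcodes, with a median of 1290 UMIs and 729 genes. The Laptm5KO56R expression library held 13090688 UMIs over 6508 barcodes, with a median of 1514 UMIs and 833 genes. The receptor libraries held 17904 contigs with 107297 UMIs in 56R and 24301 contigs with 192387 UMIs in Laptm5KO56R. Each genotype had 1 library per assay and no replicates, so all differences below are between 2 libraries, and intervals cover counting error only. Both libraries are labelled male, but the 56R library held 2544 UMIs of the X-inactivation transcript Xist and the Laptm5KO56R library held 0. Among kept cells, 1101 of the 56R cells (21.8%) had an Xist UMI.

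The knocked-out gene was measured first, as a check of the labels. Laptm5 (ENSMUSG00000028581, chromosome 4, 130913125 to 130936141, plus strand, GRCm38) stood at 494 CPM (95% interval 481 to 508, 4930 UMIs) in 56R cells and at 1.01 CPM (0.540 to 1.73, 13 UMIs) in Laptm5KO56R cells. The level was 487-fold higher in 56R (285 to 916). In 56R it was found in each of the compared B-lineage classes, from 357 CPM in mature B-like cells to 555 CPM in small pre-B-like cells. It was highest among the classes measured in plasmacytoid dendritic-like cells, at 940 CPM, where 0 UMIs were found in Laptm5KO56R.

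The class comparison asked how the stages of marrow B cell development differed in their share of B-lineage cells when LAPTM5 was missing. The Laptm5KO56R library held relatively fewer early, dividing B-lineage cells and more late ones. Cycling pre-B-like cells, led by mitotic genes such as Ccnb2 and Ube2c and by histone genes, made up 38.2% of 2116 B-lineage cells in 56R (36.1 to 40.3%) and 20.8% of 3487 in Laptm5KO56R (19.5 to 22.2%). Pro-B-like cells, which carried the surrogate light chain genes Igll1, Vpreb1 and Vpreb2, made up 9.07% (7.88 to 10.4%) and 5.22% (4.50 to 6.01%). Small pre-B-like cells, led by the recombinase gene Rag1 and by Il2ra, made up 19.99% (18.3 to 21.8%) and 30.03% (28.5 to 31.6%). Cluster 4, led by Ms4a1, Tnfrsf13c, Fcmr, Ltb, Cd79a and Bank1, with markers of both immature and mature B cells, made up 16.02% (14.5 to 17.7%) and 21.7% (20.4 to 23.1%). Mature B-like cells, led by Jchain, Fcmr, Fcer2a, Cd55 and Cr2, made up 15.6% (14.1 to 17.2%) and 21.2% (19.9 to 22.6%). Nearly all Jchain UMIs of this class, a plasma cell transcript, came from 7 cells in 56R and 14 in Laptm5KO56R. A small unnamed cluster with Nr4a1, Myc and Cd83 made up 1.13% and 1.004%.

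**Figure D1:**
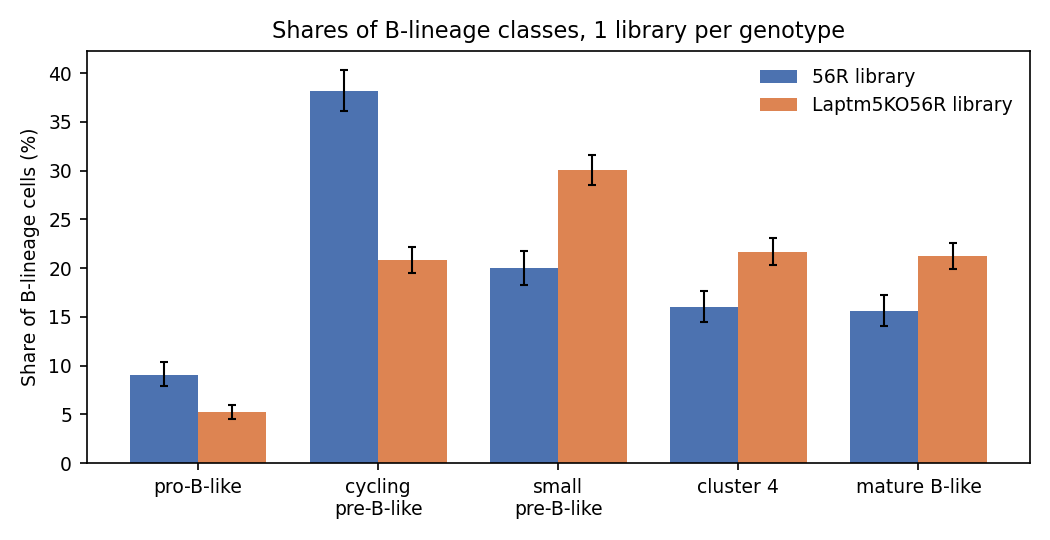
Share of B-lineage cells (%, vertical axis) in 5 classes (horizontal axis), with 1 bar per library and exact binomial 95% intervals as error bars. Cycling pre-B-like cells stand at 38.2% in 56R and 20.8% in Laptm5KO56R, and small pre-B-like cells at 19.99% and 30.03%.

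Pro-B-like and cycling pre-B-like cells together made up 47.3% of B-lineage cells in 56R and 26.0% in Laptm5KO56R, a difference of -21.2 percentage points (-23.8 to -18.6). Small pre-B-like cells and cluster 4 together made up 36.0% and 51.7%, a difference of 15.7 points. With at least 200 genes and at most 20% mitochondrial UMIs per barcode these differences were -12.1 and 7.15 points, and that of cluster 4 was 1.96 points against 5.69. The pro-B-like cells also expressed the proliferation gene Mki67 at 703 CPM and had little of the pro-B cell polymerase Dntt, 54.5 CPM. The 56R library was shallower and lost more barcodes to the gene minimum, and with all Laptm5KO56R cells thinned to 0.740 of their UMIs, the ratio of medians in cycling pre-B-like cells, the difference in early cells was -10.6 points (-13.5 to -7.76) and that in mature B-like cells turned to -1.27 points. That ratio was 0.926 in cluster 4 and 1.01 in mature B-like cells, and with each class thinned by its own ratio the differences in early and mature B-like cells were -20.6 and 6.45 points. The boundary between small pre-B-like cells and cluster 4 was unstable: with the 5 and 3 cells that Scrublet marked as doublets kept, and the cells clustered again, the differences were 1.74 and 13.02 points, and with expression centred per library that of cluster 4 was -1.70 points.

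Cells outside the B lineage passed the magnetic enrichment in both libraries, and their shares depend on it. B-lineage cells were 42.0% of kept cells in 56R (40.6 to 43.3%) and 56.8% in Laptm5KO56R (55.6 to 58.1%), a difference of 14.9 points that was 7.66 points after thinning by 1 ratio and 14.8 after thinning by that of each class. Plasmacytoid dendritic-like cells, which express B220 in the mouse, made up 26.9% and 20.4% of kept cells. T or NK cell-like cells made up 10.3% and 8.78%, neutrophil-like cells 5.04% and 2.72%, monocyte or macrophage-like cells 3.57% and 2.95%, and erythroid-like cells 2.02% and 0.668%. The 3 unnamed clusters outside the B lineage held 3.33% and 3.93% (dendritic and B cell genes together), 3.27% and 2.13% (dendritic precursor genes) and 3.65% and 1.55% (mixed myeloid and platelet genes).

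Within classes, the comparison asked which transcripts differed in cells of the same stage. A difference shared by the 4 compared classes was in protein chaperones. Of 632 genes measured in all 4 compared classes, 5 were at least 1.5-fold higher in Laptm5KO56R in every class, and 3 of these were chaperones. Dnaja1, Hspa8 and the lower Ifi27l2a stayed past 1.5-fold in every class under each alternative run, whereas Hspa5 (lowest 0.43 on the log2 scale), Rsrp1 (0.46) and Tsc22d3 (0.57) fell short of it in 1 or more. Dnaja1, a co-chaperone of the HSP40 family (ENSMUSG00000028410, chromosome 4, 40722150 to 40737149), was 2.17-fold higher in cycling pre-B-like cells (1.87 to 2.52), 2.17-fold in small pre-B-like cells (1.70 to 2.79), 2.46-fold in cluster 4 (1.91 to 3.19) and 3.99-fold in mature B-like cells (3.02 to 5.37). Hspa8, the constitutive cytosolic HSP70 (ENSMUSG00000015656, chromosome 9, 40800984 to 40810087), was higher by 1.85-fold (1.73 to 1.97), 2.22-fold (1.92 to 2.56), 2.64-fold (2.28 to 3.07) and 2.38-fold (2.09 to 2.70) in the same order. Hspa5, the endoplasmic reticulum HSP70 known as BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), was higher by 1.59-fold, 1.61-fold, 2.15-fold and 1.79-fold. Without mature B-like cells rich in Jchain, Hspa5 was higher there by 0.46 on the log2 scale against 0.84 with them. Tsc22d3, a glucocorticoid-induced gene, was higher by 1.52-fold to 2.24-fold, and Rsrp1 by 1.52-fold to 2.06-fold. Ifi27l2a, an interferon-inducible gene (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680), was the only one of these 632 genes that was at least 1.5-fold lower in every class. Gm42031 was lower by as much in all 4 classes too, but did not reach 200 UMIs in mature B-like cells, and Xist was at 0 in Laptm5KO56R. Ifi27l2a was 1.95-fold higher in 56R in cycling pre-B-like cells, 2.28-fold in small pre-B-like cells, 2-fold in cluster 4 (1115 CPM against 557) and 2.003-fold in mature B-like cells.

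**Figure D2:**
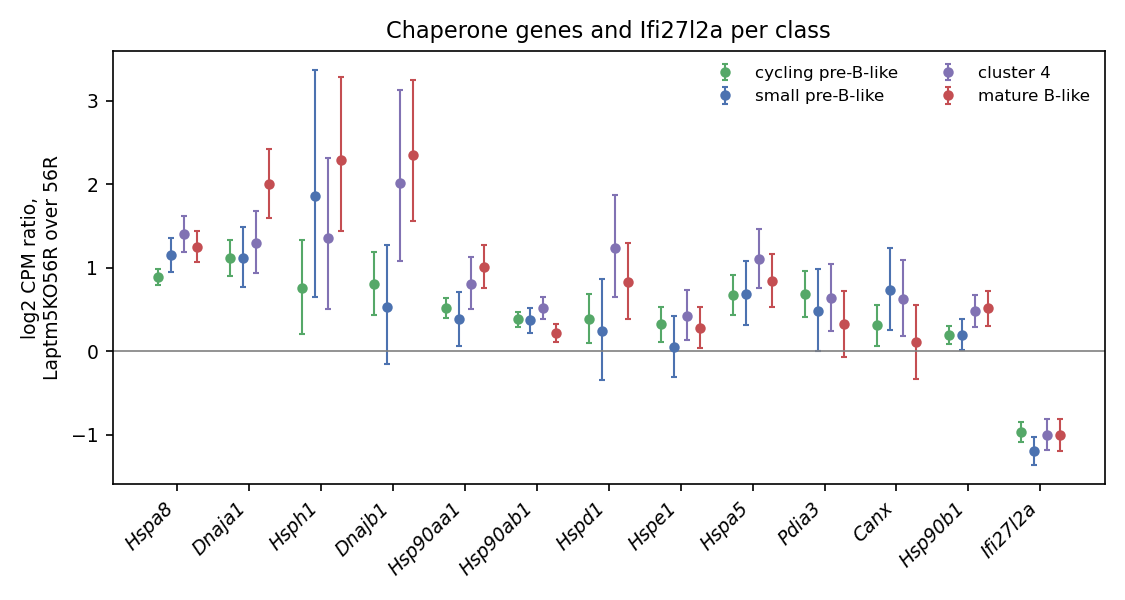
log2 ratio of CPM, Laptm5KO56R over 56R (vertical axis), for 12 chaperone genes and Ifi27l2a (horizontal axis), with 1 point per class and exact 95% counting intervals as error bars. Hspa8 lies between 0.89 and 1.40 and Dnaja1 between 1.12 and 1.997 in the 4 classes, and Ifi27l2a between -1.19 and -0.96.

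The fixed heat shock list was higher as a group. All 8 measured members were higher in cycling pre-B-like cells, in small pre-B-like cells (5 with an interval above 1) and in cluster 4, and all 10 in mature B-like cells. The median log2 ratio was 0.64, 0.46, 1.27 and 1.62 in that order, at percentiles 100, 99.97, 100 and 100 of random lists. With members of at least 200 UMIs the last 2 medians were 0.81 and 0.92, and the mature B-like median includes Hspa1a and Hspa1b, which had 1 UMI each in 56R. Dnajb1 was higher by 2.02 on the log2 scale in cluster 4 (1.08 to 3.12) and by 2.35 in mature B-like cells (1.56 to 3.25), and Hsph1, an HSP110 chaperone, by 1.35 and 2.29. The unfolded protein response list was also higher, with medians of 0.36, 0.26, 0.52 and 0.32 and percentiles of 100, 98.7, 100 and 99.9. All 16, 14 and 15 measured members had a ratio above 1 in the first 3 of these classes, with an interval above 1 for 10, 6 and 8. In mature B-like cells 14 of 15 did, 5 with an interval above 1, and Edem1 was lower (-0.55, -1.08 to -0.02). Pdia3, a protein disulfide isomerase, was higher by 0.68, 0.48, 0.63 and 0.32, and Hsp90b1 by 0.19, 0.20, 0.48 and 0.51. Xist-positive cells made up part of the 56R library, and without them the heat shock median in cluster 4 was 1.21. Across the 4 classes, 92 comparisons of the fixed lists were computed, and those of the marker lists came on top of these. Some percentiles near 0 or 100 would therefore arise by chance.

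In cluster 4, the 12 highest genes included 6 chaperones or folding enzymes: Hspa8, Dnaja1, Hspa5, Hsp90aa1 (1.75-fold, 1.42 to 2.18), Hsp90ab1 (1.43-fold, 1.30 to 1.56) and Pdia6 (1.75-fold, 1.31 to 2.39). The others were Luc7l3, a splicing factor (2.32-fold, 1.60 to 3.46), Cacybp (2.19-fold), Dynll1 (1.81-fold), the survival kinase Pim2 (1.82-fold, 1.29 to 2.63), Atf7ip (1.76-fold) and Prelid1 (1.67-fold). The 12 lowest included the lincRNA Gm42031 (-1.30 on the log2 scale, -1.65 to -0.95), Ifi27l2a and the cold-inducible RNA-binding gene Cirbp (-0.97, -1.37 to -0.58). They also included the MHC class II genes H2-Eb1 (-0.40, -0.53 to -0.26) and H2-Oa (-0.65, -1.05 to -0.24) and Cd22, an inhibitory co-receptor of B cells (-0.62, -1.01 to -0.22). Pet100, Maf1, Fus, Malat1, Snrpg and Srsf5 completed them, from -0.73 for Maf1 to -0.32 for Malat1. With doublets kept and the cells clustered again, Hsp90aa1 stood at 0.45, Pdia6 at 0.43, Hsp90ab1 at 0.21, Fus at -0.37, Maf1 at -0.25 and Malat1 at -0.10 on the log2 scale.

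In cycling pre-B-like cells, Dnaja1, Hspa8, Dnajb1 (1.75-fold), Tsc22d3 (2.24-fold), Rsrp1 (1.69-fold) and the chromatin remodeller Chd1 (1.68-fold) were highest. Gm42031 (-1.41) and Ifi27l2a (-0.96) were among the lowest, beside Xist, at 434 UMIs in 56R and 0 in Laptm5KO56R. Jchain was also among them, but 374 of its 376 UMIs in 56R and 237 of 240 in Laptm5KO56R came from 1 cell in each library, and without such cells its ratio was 0.29. The histone genes H2ac18 (-0.79) and H2ac12 (-0.96) were lower, and related histone genes define part of this class. In small pre-B-like cells, Hspa8, Dnaja1, the chaperonin gene Cct8 (2.07-fold, 1.44 to 3.05), Rsrp1, the phosphatase gene Ptpn6, which restrains receptor signalling (1.96-fold, 1.40 to 2.82), and Tmem128 (1.93-fold) were highest. Ifi27l2a, Gm42031 (-1.04), Hnrnpd (-0.92), Lgals1 (-0.73), Hmgn2 (-0.70) and H2-Ab1 (-0.64) were lowest. In mature B-like cells, Dnaja1, the HSP90 co-chaperone Ahsa1 (3.56-fold, 2.28 to 5.82), Hspa8, Hsp90aa1 (2.01-fold, 1.68 to 2.42), Rsrp1 and Hspa5 were highest. Ifi27l2a, Fus (-0.79), Romo1 (-0.76), the inhibitory receptor gene Btla (-0.70) and Ncl (-0.55) were lowest. Hist1h2ap was also among the lowest (-1.34), but its ratio was 0.19 with doublets kept, where Ncl stood at -0.26 and Ifi27l2a at -0.63 and, in small pre-B-like cells, Tmem128 at 0.60.

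Glycolysis genes had medians of 0.43 in cycling pre-B-like cells (11 of 11 members higher, 7 with an interval above 1), 0.50 in small pre-B-like cells (8 of 9, 5 with such an interval) and 0.31 in cluster 4 (8 of 9, 2 with such an interval), and of 0.04 in mature B-like cells (6 of 10, 1 with such an interval). The difference between classes was not tested. Gapdh was higher by 0.48, 0.49 and 0.39 and Ldha by 0.46, 0.58 and 0.30 in the first 3 of these classes. The FOXO program, which includes genes of recombination and homing, had medians of 0.09, 0.30, 0.25 and 0.24, at percentiles 76.0, 99.96, 99.1 and 93.4, the third of which was 93.0 with members of at least 200 UMIs. In it, Rag1 was higher in small pre-B-like cells (0.56, 0.34 to 0.78), the quiescence factor Klf2 was higher in all 4 classes by 0.30 to 0.42, and the homing receptor Ccr7 was higher by 0.37 to 0.79, with intervals above 0 in cycling pre-B-like and mature B-like cells. The interferon response list was lower in cycling pre-B-like cells (-0.29, percentile 0.295) and cluster 4 (-0.30, percentile 0.17), but stood inside the random range at -0.16 (percentile 6.34) in the former with members of at least 10 UMIs and at -0.15 (9.05) in the latter with at least 200. Its median was -0.27 in small pre-B-like cells, where it turned to 0.08 and 0.15 at other UMI minima, and -0.01 in mature B-like cells. Only Ifi27l2a and, in some classes, Bst2 and Ly6a had intervals below 0, and Ly6e was higher in cycling pre-B-like cells (0.21). MHC class II genes were lower in cluster 4 (-0.22, percentile 0.54, 7 of 10 members lower, 5 with an interval below 1) and higher in mature B-like cells (0.20, percentile 97.7, 9 of 10 higher, 5 with an interval above 1), with 0.08 and -0.03 in the cycling and small pre-B-like cells. The marker lists of immature and mature B cells, which share H2-Aa, H2-Ab1, H2-Eb1 and Cd74 with this list, had the same signs. Immature B markers had medians of -0.28 in cluster 4 (percentile 0.065) and 0.21 in mature B-like cells (98.98), and mature B markers -0.14 (2.37) and 0.21 (99.3). Cd74, the invariant chain, was higher in all 4 classes by 0.21 to 0.40.

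The list of BAFF receptors and maturation had medians of -0.01, -0.06, -0.01 and 0.21, the last at percentile 98.0 (77.9 with members of at least 10 UMIs), and its member Tnfrsf13c, the BAFF receptor, was higher in mature B-like cells (0.80, 0.43 to 1.19). Ighd, the constant region of IgD, was lower in small pre-B-like cells (-0.72), cluster 4 (-0.95, -1.20 to -0.70) and mature B-like cells (-0.32). The immunoglobulin constant list had medians of -0.04, -0.06, -0.16 and -0.32, the last of which stood at percentile 0.035 and was -0.12 without cells rich in Jchain. Igkc was lower in all 4 classes, from -0.19 to -0.48.

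The PI3K-AKT-PTEN and NEDD4 ligase list, fixed because it holds proposed partners of LAPTM5, had medians of -0.04, 0.02, 0.12 and -0.09, all inside the random range. Pten stood at -0.04, -0.33, 0.17 and -0.13 and Wwp2 at 0.09, 0.02, -0.42 and 0.29, with all of these intervals reaching 0. The proapoptotic list had medians of 0.07, 0.00, -0.01 and -0.20 over 3 to 6 measured members, and Bcl2l11, which encodes BIM, was lower in mature B-like cells (-0.90, -1.69 to -0.10). The antiapoptotic list stood at -0.00088, 0.0042, -0.08 and -0.30, the last at percentile 2.09. Receptor signalling genes had medians of 0.12, 0.17, 0.07 and 0.18 and p53 targets 0.26, 0.11, 0.22 and 0.36, with Cdkn1a higher in cycling pre-B-like cells (0.72, 0.33 to 1.11). Medians were 0.19, 0.26, 0.09 and 0.14 for immediate early genes, 0.09, 0.01, -0.01 and 0.29 for NF-kB targets, and 0.03, 0.00, -0.04 and 0.01 for recombination and editing. They were -0.02, -0.13, -0.19 and 0.26 for the surrogate light chain, 0.04, -0.10, 0.17 and -0.28 for cell cycle, and -0.10, -0.06, -0.03 and 0.12 for MHC class I. They were 0.07, 0.22, 0.07 and 0.04 for the lysosome, 0.03, 0.08, 0.15 and 0.15 for migration, -0.06, -0.13, -0.09 and -0.09 for mitochondrially encoded genes, and -0.08, -0.05, -0.11 and -0.07 for ribosomal proteins. Of the medians in these last lists, those outside the random range were p53 targets (percentile 98.5), MHC class I (2.3) and ribosomal proteins (0.17) in cycling pre-B-like cells, receptor signalling (98.7) and the lysosome (99.2) in small pre-B-like cells, and ribosomal proteins (0.01) in cluster 4. In mature B-like cells they were receptor signalling (98.7), NF-kB targets (97.9), cell cycle (1.42) and the antiapoptotic list. With members of at least 10 UMIs, NF-kB targets (75.8) and the antiapoptotic list (7.56) fell inside that range, as did MHC class I (9.18), the lysosome (96.8) and receptor signalling in mature B-like cells (88.2) with at least 200. The neutrophil transcripts S100a8 and S100a9, found at low levels in B-lineage cells, were lower in Laptm5KO56R in all 4 classes, S100a9 by ratios from -0.95 to -1.58, beside the smaller share of neutrophil-like cells in that library.

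The heavy chain comparison asked how much of the repertoire the knocked-in chain held. Heavy chain recovery was unequal, with 1573 of the 4106 cells used in 56R and 3607 of the 5310 in Laptm5KO56R, whose receptor library held more contig UMIs. Most cells with a heavy chain carried 1 CDR3, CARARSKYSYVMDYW, with IGHV1-82 and IGHJ4. It was found in 1274 of 1573 such cells in 56R (81.0%, 79.0 to 82.9%) and in 3299 of 3607 in Laptm5KO56R (91.5%, 90.5 to 92.4%). Other heavy chains with the same CDR3 ending made up 4.13% and 1.91%. IgM contigs were found in 88.6% and 95.9% of cells with a heavy chain, IgD 4.77% and 3.47%, and IgA 6.17% and 0.444%. With productive contigs of any barcode, IgA stood at 9.48% and 7.16%. In 56R, 87 called cells shared the IgA chain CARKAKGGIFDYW with IGHV2-2, which was found on 0 barcodes of Laptm5KO56R, and 7 of its 96 barcodes were in the expression library. Without that chain IgA stood at 0.673% and 0.444% (difference -0.23 points, -0.70 to 0.24). The difference in the share of the main chain was then 5.73 points against 10.5 with it, and with productive contigs of any barcode it was 4.83 points. On barcodes kept in the expression library it was 4.004 points (1.28 to 6.73) for called cells and 2.05 points (0.36 to 3.75) with contigs of any caller verdict. These barcodes came from all classes, not only from the B lineage. With contigs of any caller verdict, 301 of 1509 cells with a heavy chain in 56R and 568 of 3341 in Laptm5KO56R were plasmacytoid dendritic-like. The IgM, IgD and IgA differences on barcodes kept in the expression library all had intervals that reached 0. For called cells, IgM stood at 94.6% and 96.1%, IgD at 2.91% and 2.95% and IgA at 1.80% and 0.787%.

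The light chain comparison described which partners the heavy chain was found with, since light chain editing is a known route by which 56R B cells lose DNA binding. Lambda chains were less frequent in Laptm5KO56R, at 25.8% of 3587 cells with a light chain (24.4 to 27.3%) against 32.1% of 3433 in 56R (30.6 to 33.7%). IGLV1 stood at 16.9% in 56R and 12.9% in Laptm5KO56R, IGLV3 at 9.23% and 7.03%, and IGLV2 at 6.03% and 5.94%. Among cells that also carried the main heavy chain, lambda made up 35.2% (31.5 to 39.0%) and 30.1% (27.9 to 32.4%). The kappa genes among the 8 most used V genes were IGKV19-93, at 9.76% and 11.7%, IGKV17-121, at 9.53% and 10.5%, IGKV17-127, at 7.54% and 6.58%, IGKV1-135, at 3.18% and 3.29%, and IGKV6-23, at 2.74% and 2.90%. Among V genes with at least 50 cells over both libraries, the largest ratios of shares, Laptm5KO56R over 56R, were those of IGKV5-48 (2.13), IGKV3-4 (1.91), IGKV8-30 (1.64) and IGKV13-84 (1.48). IGLV3 (0.761), IGLV1 (0.765), IGKV8-19 (0.808) and IGKV9-120 (0.828) had the smallest. The differences in share of IGKV8-30, IGKV13-84, IGKV8-19 and IGKV9-120 had intervals that reached 0. With contigs of any caller verdict on barcodes kept in the expression library the order changed, with ratios of 3.82 for IGKV8-30, 2.05 for IGKV13-84, 1.74 for IGKV3-4 and 1.54 for IGKV5-48. The most distal joining gene, IGKJ5, was used by 26.2% and 28.1% of kappa cells (difference 1.90 points, -0.57 to 4.37), and by 27.2% and 31.1% with those contigs (3.97 points, 0.38 to 7.56). With cells limited to barcodes kept in the expression library, the IGLV1 difference was -1.14 points against -3.96 and the IGLV3 difference -6.25 points against -2.21.

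**Figure D3:**
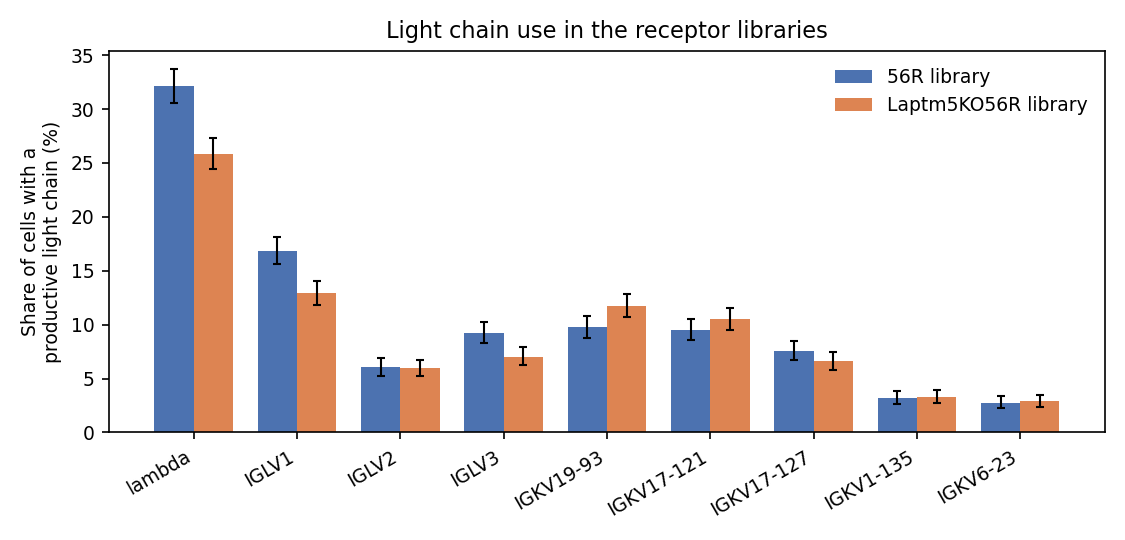
Share of cells with a productive light chain (%, vertical axis) that carry a lambda chain or each named V gene (horizontal axis), with 1 bar per library and exact binomial 95% intervals as error bars. Lambda stands at 32.1% in 56R and 25.8% in Laptm5KO56R, while IGLV2 stands at 6.03% and 5.94%.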

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

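In this part, the receptor values by class and the barcodes with several light chains come from settings chosen after the data were seen, and the MHC class II list was planned. No difference between classes was tested.

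MHC class II genes had medians of opposite sign in cluster 4, which was left unnamed, and in mature B-like cells. The median log2 ratio, Laptm5KO56R over 56R, was -0.22 in cluster 4 and 0.20 in mature B-like cells, and this difference was not tested. H2-Aa stood at -0.29 and 0.21, H2-Ab1 at -0.28 and 0.12 and H2-Eb1 at -0.40 and 0.23, while Cd74 was higher in both (0.21 and 0.22). The immature B markers stood at -0.28 and 0.21 and the mature B markers at -0.14 and 0.21. Both share H2-Aa, H2-Ab1, H2-Eb1 and Cd74 with the MHC class II list, and the make-up of cluster 4 in each library was not separated from these values.

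Barcodes with more than 1 light chain were nearly absent from the called receptor cells. At least 2 productive light chains were found on 582 barcodes in 56R and 774 in Laptm5KO56R, of which only 13 (2.23%) and 21 (2.71%) were called cells. Of barcodes with 1 productive light chain, 80.5% and 77.7% were called cells. The shares of dual light chains among called cells, 0.379% and 0.585%, therefore leave out most such barcodes. Doublets and free RNA were not separated from B cells with several light chains.

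Plasmacytoid dendritic-like cells carried heavy chain contigs, and the receptor comparisons of the report were not limited to B-lineage cells. A heavy chain contig was found in 22.2% of these cells in 56R and in 45.3% in Laptm5KO56R, and 98.3% and 99.5% of them had the main CDR3. As a background level, T or NK cell-like cells had a heavy chain contig in 7.54% and 9.28%. Heavy chains were also recovered more often in Laptm5KO56R in the 5 B-lineage classes, such as in 40.2% and 66.7% of small pre-B-like cells and 54.7% and 81.9% of pro-B-like cells, so the difference between libraries was not particular to these cells. Expression depth was similar in both cell types within each library, but higher in Laptm5KO56R than in 56R. Medians were 1301 in 56R and 1727 UMIs in Laptm5KO56R in the largest plasmacytoid dendritic-like cluster. They were 1268.5 and 1699 in the largest T or NK cell-like cluster. The receptor library of Laptm5KO56R also held more contig UMIs, 192387 against 107297. Light chain contigs were found in 2.21% and 2.55% of plasmacytoid dendritic-like cells and in 9.28% and 8.35% of T or NK cell-like cells.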

How the results depend on the processing

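The settings with thinned cells, with the highest doublet scores removed, without Xist-positive or Jchain-rich cells, without the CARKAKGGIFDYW chain, with heavy chains on barcodes of the expression library, and with contigs of any caller verdict there were chosen after the data were seen, and the others were planned. No paired analysis was possible because each genotype has 1 library per assay. A share counted as the same when it moved by less than its counting interval, and a list median when it moved by less than the distance from the middle to an end of its random range, which is a wide allowance. Of the differences in class shares, 62 values were the same, 21 moved and 2 reversed. Of named genes 466 were the same, 17 moved and 3 reversed. Of these 466, 31 came from a minimum of 500 UMIs, which leaves a ratio unchanged and so tests nothing. TMM factors and scaling without immunoglobulin, mitochondrial and ribosomal-protein genes gave 65 each, and shifted all genes of a class by at most 0.047 on the log2 scale. Of the main lists 115 were the same, 3 moved and 2 reversed, and of the other lists 321 were the same and 4 moved. For the main heavy chain 1 value was the same and 6 moved, and for isotypes and the other heavy chain 12 were the same, 14 moved and 2 reversed. For lambda 5 were the same and 1 moved, while of named V genes and other light chain shares 77 were the same and 19 moved. The fold of Laptm5 was 463 over all barcodes. No setting reversed the lower share of early cells in Laptm5KO56R.

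Differences in shares are in percentage points, Laptm5KO56R minus 56R. With at least 200 genes and at most 20% mitochondrial UMIs they were 11.1 for all B-lineage cells, -12.1 for pro-B-like and cycling pre-B-like cells together and for cycling cells, into which the pro-B-like cells merged, 7.15 for small pre-B-like cells and cluster 4 together, 5.19 for small pre-B-like cells and 1.96 for cluster 4. With Laptm5KO56R thinned by 1 ratio for all classes they were 7.66 for all B-lineage cells, -10.6 for early cells, -1.69 for pro-B-like and -8.93 for cycling pre-B-like cells, 11.97 for small pre-B-like cells and cluster 4 together, 7.30 for small pre-B-like cells and -1.27 for mature B-like cells. With each class thinned by its own ratio none moved, and early cells stood at -20.6, so the effect of thinning depends on the ratio used. All thinning ratios come from cells already past the minima. Those of each class left 740 of 740 mature B-like cells, so few late cells could drop out. Centring per library gave 11.5 for small pre-B-like cells and cluster 4, 13.2 and -1.70 for each, and 8.42 for mature B-like cells. Keeping the 5 and 3 cells marked as doublets gave 1.74 for small pre-B-like cells and 13.02 for cluster 4, and keeping immunoglobulin genes gave 7.40 and 9.01. Cycling pre-B-like cells stood at -21.7 with at most 5% mitochondrial UMIs and -21.4 at resolution 0.6, where the pro-B-like cells merged into them. Apart from thinning and merging, the cause was not tested.

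On the log2 scale, Hist1h2ap in mature B-like cells was 0.19 with doublets kept. Jchain in cycling pre-B-like cells was 7.20 without Xist-positive cells and 0.29 without Jchain-rich cells, since 1 cell per library held nearly all of its UMIs. The interferon list in small pre-B-like cells was 0.080 with members of at least 10 UMIs and 0.15 with at least 200, and the unfolded protein response list there was 0.48 with at least 10. With at least 200 UMIs the heat shock list was 0.81 in cluster 4 and 0.92 in mature B-like cells, as fewer members were measured. The difference in the main heavy chain was 13.9 points at 5 UMIs or more, 4.83 with contigs of any barcode, 14.3 in cells with 1 heavy and 1 light chain, 5.73 without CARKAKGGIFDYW, and 4.004 and 2.05 on barcodes kept in the expression library, for called cells and for contigs of any caller verdict, and that in lambda was -9.66 in cells with 1 heavy and 1 light chain. The IgD difference was 0.35 points at 5 UMIs or more and 0.039 on called barcodes kept in the expression library, against -1.30. The cause was not tested for the contig settings. Receptor use by class has no value under the planned rule, since the libraries were not joined, and no list median could be had at 200 UMIs where too few members passed. Recovery of lowered genes was limited: in simulated counts, 56% of genes lowered 2-fold were recovered in cluster 4 and 70% in cycling pre-B-like cells. Of raised genes, 100% were recovered in both, and the part that depth plays was not tested.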

Other observations

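The tests of handling, of Xist-positive cells on chaperones, of LAPTM5 loss, of thinning by each class and of Xist itself were chosen after the result was seen, as was the join of receptors to classes, while those of Rbm3, of thinning by 1 ratio and of Y-linked cells on shares were chosen before their results were seen.

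Lambda use differed between the libraries in mature B-like cells and was close in cluster 4 when productive contigs of at least 2 UMIs were placed on the classes by barcode, a setting that the planned rule did not allow. The difference between the classes was not tested. Among mature B-like cells with a light chain, lambda was found in 33.7% in 56R and 19.7% in Laptm5KO56R, and IGLV3 in 27.6% (22.8 to 32.8%) and 13.7% (11.3 to 16.4%). At least 2 light chains were found in 29.7% and 20.2% of these cells. In T or NK cell-like cells with a light chain they were found in 6.25% and 22.2% (3 of 48 and 10 of 45). Doublets and free RNA were not separated from B cells with 2 light chains. In cluster 4, lambda stood at 32.1% and 32.2% and at least 2 light chains at 30.1% and 28.4%. The main heavy chain made up 84.0% and 93.3% of heavy chains in cluster 4, where a heavy chain was recovered in 55.5% and 74.8% of cells. In mature B-like cells it made up 79.9% (72.5 to 86.0%) and 76.7% (72.5 to 80.5%), with overlapping intervals. Small pre-B-like cells used IGKJ5 in 23.6% (16.5 to 32.0%) and 32.2% (27.4 to 37.3%) of kappa cells. IGLV3 in mature B-like cells stood at 43.9% (30.7 to 57.6%) in 56R cells with an Xist UMI, 29.6% (13.8 to 50.2%) in 56R cells with a Y-linked UMI and 14.4% (9.02 to 21.3%) in Laptm5KO56R cells with a Y-linked UMI.

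The chaperone difference was not limited to the B lineage. Hspa8 was higher in Laptm5KO56R in 14 of the 14 classes measured, by 1.62-fold to 2.64-fold, each with an interval above 1, and Dnaja1 was higher in 14, of which 13 had an interval above 1. Ifi27l2a was lower in 13 of 14 classes and Cirbp in 12, with intervals below 1 in 11 and 9, and Ifi27l2a was higher in neutrophil-like cells (1.60-fold, 1.13 to 2.28). A cluster of plasmacytoid dendritic-like cells led by Hspa1b and Hspa1a held 96 Laptm5KO56R cells and 1 cell of 56R. Rsrp1, higher in all 4 compared classes, starts 4.01 Mb from Laptm5, and had the largest ratio among genes within 5 Mb of Laptm5 in each of them. The median size of the log2 ratio in that window was 0.13, 0.19, 0.16 and 0.09 in cycling pre-B-like cells, small pre-B-like cells, cluster 4 and mature B-like cells, against 0.15, 0.16, 0.16 and 0.18 for other genes.

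Higher chaperone transcripts in every compared B-lineage class may reflect how the suspensions were handled. In erythroid-like cells, where Laptm5 stood at only 27.5 CPM in 56R, Hspa8 was still 1.78-fold higher in Laptm5KO56R (1.63 to 1.95). There the heat shock list had the smallest median of the 14 classes, 0.27, with intervals above 1 for 5 of 8 members, while those of Dnaja1 (1.13-fold, 0.84 to 1.49), Hsp90aa1 (1.11-fold, 0.99 to 1.24) and Hspe1 reached 1. The cold-inducible Rbm3 was lower in 3 of the 4 compared classes, although it was higher in cycling pre-B-like cells (1.12-fold) and erythroid-like cells (1.20-fold). Without 56R cells with an Xist UMI, the heat shock median in cluster 4 was 1.21, so cells with a detected Xist UMI did not account for it. A mixture of mice stays open, because cells with no detected Xist UMI could still come from female mice. Chaperones were not compared in cells with a Y-linked UMI. Loss of LAPTM5 also stays open and cannot be told apart from handling, because each genotype has 1 expression library.

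The smaller share of pro-B-like and cycling pre-B-like cells in Laptm5KO56R could follow from depth, from a mixture of mice or from loss of LAPTM5. Thinning could not decide whether depth and the minima were the whole cause, because its ratios come from cells already past the minima. The difference was -10.6 points (-13.5 to -7.76) after thinning by the ratio of medians in cycling pre-B-like cells, against -21.2 before. A difference thus remained at that ratio, which left 351 of 740 mature B-like cells. A lower ratio for all classes was not tested. The difference was -20.6 after thinning by the ratio of each class. That setting left 740 of 740 mature B-like cells and 723 of 757 cells of cluster 4, so it could hardly test depth. A mixture with Xist-positive cells was argued against as the whole cause. 56R cells with a Y-linked UMI and no Xist UMI had 49.3% early cells (43.5 to 55.2%). Laptm5KO56R cells with a Y-linked UMI had 33.7% (30.4 to 37.2%). However, 56R cells with an Xist UMI and no Y-linked UMI had 58.8% early cells (53.7 to 63.7%). Loss of LAPTM5 stays open and untested with 1 library per genotype.

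Xist in a library labelled male is consistent with cells of female mice in the 56R pool. Cells with an Xist UMI had Y-linked UMIs at 0.158 times the share of other 56R cells (0.110 to 0.226), and 30 cells had both, where 155 would be expected by chance. Free Xist RNA spread over droplets was argued against, since cells with a Y-linked UMI had Xist at 0.171 times the share of the others (0.120 to 0.244). No biological explanation within male cells was tested.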
